A study of Ipomoea batatas with 12 samples.

How the data were processed

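Messenger RNA was measured by sequencing in sweet potato (Ipomoea batatas, cultivar Tainong 57) leaves, in 12 libraries. Per the labels, the third leaf of plants grown from scions was treated for 1 h with water, with the peptide IbHypSysIV or with the peptide IbPep1, and 4 libraries were made for each. RNA was extracted with TRIzol, per the labels' protocols, which name both a NEBNext Ultra kit and a SMARTER kit for library construction and do not say which library was made with which. Nothing in the labels says whether the libraries or the counting kept strand, so reads of overlapping or antisense genes cannot be told apart. Each library was placed in its group by its source name. For replicates 1, 2, 3 and 4 of IbPep1 a separate treatment field reads IbPep1, IbPep2, IbPep3 and IbPep4, while the source name reads IbPep1 for all 4 and the treatment protocol names no other peptide besides IbHypSysIV. The titles of all 4 begin with the code P2, which the labels do not explain. A field filled by counting up and a peptide other than IbPep1 both remain possible, and these libraries were kept as IbPep1 by their source name. Replicates are numbered in accession order within a group, and these numbers pair nothing. The labels do not say that replicates came from separate plants, so the p-values measure the spread between these samples, which may be partly technical.

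The deposited table holds raw read counts per gene, as whole numbers, in 1 column per library for 32301 gene identifiers. HISAT2 2.0.5, HTSeq 0.6.1 and DESeq2 1.22.2 are named in the submitters' processing notes. The genome build and the gene annotation are not given in the sources used here. Total counts ranged from 16607188 to 25073251 per library, so that 3 counts, the floor used here, correspond to 0.120 to 0.181 CPM (counts scaled to the library total). This floor covers counting error only, since reads copied by PCR are not independent molecules. The table does not pair identifiers with gene names, and 0 of the 32301 identifiers matched the reference gene table that was searched. For that reason 32 gene lists fixed before the data were examined, written as patterns on product descriptions, could not be used (0 were used), and at most 2 identifiers that rose and 2 that fell are printed per comparison. Without sequences or gene descriptions it was not known which genes have near-identical copies that share reads, so each named identifier is uncertain in that respect.

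All analyses started from the deposited counts and ran in R 4.3.3. Genes were filtered with filterByExpr in edgeR 4.0.16, which kept 23193 genes holding 99.9% of all counts, removed 9108 and thereby left out the 2916 genes with no count in any library. Libraries were scaled by TMM factors, which ranged from 0.914 to 1.10. The CPM levels of genes, the log2 CPM and the shares of reads in called genes were scaled to the total of the kept genes times this factor. The floor was not, so it is on a slightly different scale. The 3 groups were fitted in 1 model with group as the only term, in which all 12 libraries share 1 estimate of the spread. Each comparison was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over the 23193 genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F value, and 95% intervals from the SE. Fitted fold changes use edgeR's prior count of 0.125, so those of genes near the floor depend on it. The biological coefficient of variation was 27.2%. Principal components and correlations between libraries were computed on log2 CPM with a prior count of 2.

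The named identifiers follow a rule set before the data were examined: the largest fold changes each way among called genes with a mean of at least 1 CPM over the 8 libraries compared and with no overlap between the 2 groups. The rule also asked for an informative gene name, which no identifier has. For the overlap between the peptides, 20 simulations drew unchanged groups against shared controls, and the 4 water libraries were also split into 2 and 2 in all 6 assignments. Chance was checked by refitting every split of the 8 libraries of a comparison into 4 and 4, 35 in each. The procedure was tested on simulated counts drawn from the real means, with 200 genes changed in each comparison. For IbHypSysIV against water it recovered 81.8% of the genes changed 4-fold, 31.3% of those changed 2-fold and 2.99% of those changed 1.5-fold. The same shares were 86.4%, 35.8% and 1.49% for IbPep1 against water, and 87.9%, 23.9% and 4.48% for IbPep1 against IbHypSysIV. False calls made up 2.53%, 3.53% and 4.94% of the simulated calls in the same order. Most simulated changes of 2-fold or less were therefore missed at 4 libraries per group. Only 200 genes were changed, which makes the adjusted threshold stricter than where many genes change. Genes were also drawn independently, without differences shared by a whole library. The recovered and false shares therefore do not carry over to the real comparisons.

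Alternatives were DESeq2's size factors and upper-quartile scaling in place of TMM, no filter beyond a count above 0, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of only the groups compared, a replicate block on the number in the titles, a threshold of 0.01, and leaving out each library in turn. All were chosen before the data were examined, except 1 that leaves out 3 libraries together. The titles also carry library numbers, which run in a separate range for each group, so a library batch and the group cannot be told apart.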

Results

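The series compared messenger RNA levels in sweet potato leaves after 1 h with water or with 1 of 2 peptides. IbHypSysIV bears the name of the hydroxyproline-rich systemins, and IbPep1 that of the plant elicitor peptides. Both are families of plant signalling peptides known to induce defence responses, and elicitor peptides are regarded as damage-associated molecular patterns. The series' title concerns a receptor for such a pattern and its peptide ligand. Each treatment was represented by 4 libraries, with total counts of 20243058 to 23898419 in water, 16607188 to 25073251 in IbHypSysIV and 19862106 to 23153078 in IbPep1. The most abundant gene took 1.61% to 3.87% of the counts of a library. No pair of libraries within a group agreed within sampling noise, with a chi-square per degree of freedom of at least 13.5 over genes, so none was treated as a copy of another.

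The first principal component held 35.2% of the variance and the second 17.6%. The IbPep1 libraries lay at 39.1 to 69.0 on the first component, and 3 of the water libraries at -57.1 to -37.3. Water replicate 3 lay at 40.0, within the range of the IbPep1 libraries. Across genes, its correlation with the other water libraries was 0.937 to 0.951, against 0.980 to 0.985 among those 3, and its correlation with the IbPep1 libraries was 0.955 to 0.959. IbHypSysIV replicate 4 and IbPep1 replicate 3 stood apart from their groups on the second component, at 74.9 and 32.1.

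**Figure D1:**
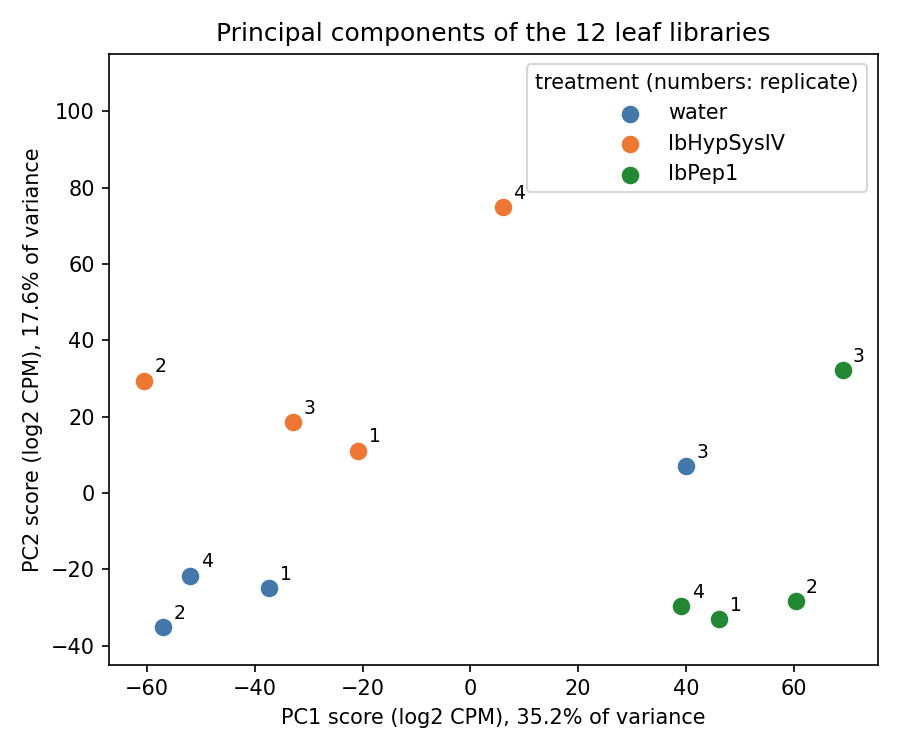
Scores of the 12 libraries on the first 2 principal components of log2 CPM, coloured by treatment and numbered by replicate. Water replicate 3 sits at 40.0 on the first component, among the IbPep1 libraries, while the other water libraries lie at -37.3 or below.

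The first comparison asked which leaf genes respond to IbHypSysIV within 1 h. Of 23193 genes tested, 282 were higher and 254 lower than in water, 536 in all, and 256 of these changed at least 2-fold. The median change was 1.95-fold among the genes that rose and 1.99-fold among those that fell, and 42 genes changed at least 4-fold, 31 of them upward. Together, the genes that rose took 0.905% ± 0.0570 of the TMM-scaled reads in water and 1.87% ± 0.106 with IbHypSysIV (SD, n = 4). Those that fell went from 1.37% ± 0.128 of the TMM-scaled reads to 0.685% ± 0.0399 (SD, n = 4).

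By the rule for named genes, the largest rise was that of itf05g06830, from 4.84 ± 4.01 CPM in water to 157 ± 60.6 CPM with IbHypSysIV (SD, n = 4), a log2 fold change of 5.03 (SE 0.73, adjusted p = 0.00995, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The gene itf05g06850, with a nearby identifier, rose from 35.4 ± 29.7 to 537 ± 222 CPM, a log2 fold change of 3.92 (SE 0.76, adjusted p = 0.0243, same edgeR test). Its call was lost without water replicate 1, water replicate 4 or IbHypSysIV replicate 3, where the log2 fold change was 3.77, 4.06 and 3.75, and in a fit of only the 2 groups, where it was 3.92. Without water replicate 2 it was 4.51 and still passed. Over all alternatives its adjusted p ranged from 7.45e-05 to 0.193. Among the genes that fell, itf03g18270 went from 35.3 ± 12.4 to 3.16 ± 1.53 CPM (11.3-fold lower, log2 -3.49, SE 0.48, adjusted p = 0.00754, same edgeR test). The level of itf05g22090 went from 132 ± 58.6 to 12.4 ± 3.67 CPM (10.7-fold lower, log2 -3.42, SE 0.40, adjusted p = 0.00296, same edgeR test).

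Of the 536 genes, 97.4% had no overlap between the 4 treated and the 4 water libraries. The share was 11.7% over all genes tested, and chance gives 2.86% for a gene not chosen by a test. The 536 were called for a difference between these same libraries. Their share therefore follows largely from the choice and is no separate support. The count depended on single libraries: it was 52, 112 and 970 without water replicates 1, 2 and 3, 34 without IbHypSysIV replicate 3 and 267 without IbHypSysIV replicate 4, and without water replicate 4 it fell to 47 genes higher and 74 lower. Without water replicate 1 or 2 fewer genes were higher than lower (25 and 27, 45 and 67). Without water replicate 3, 469 of the 536 calls remained. DESeq2 called 1779 genes, and a fit of the 8 libraries of these groups alone called 175. The replicate block on the title numbers called 0, with 3 residual degrees of freedom in place of 9. Water replicate 3 and IbHypSysIV replicates 3 and 4 have numbers found in 1 group only and add nothing to that fit's comparison.

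The second comparison asked the same of IbPep1. Leaves treated with IbPep1 differed from water in 2670 genes, 1277 higher and 1393 lower, of which 572 rose and 464 fell at least 2-fold. More genes were higher than lower with upper-quartile scaling (1445 and 1274) and with limma-voom (1350 and 1223), so the balance of directions depends on the method. The median change was 1.91-fold upward and 1.75-fold downward, and 218 genes changed at least 4-fold, 97 of them downward. The genes that rose took 3.30% ± 0.553 of the TMM-scaled reads in water and 5.95% ± 0.416 with IbPep1 (SD, n = 4). Those that fell took 7.38% ± 1.00 in water and 4.02% ± 0.169 with IbPep1 (SD, n = 4).

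By the rule for named genes, the largest rises were those of itf06g10940 (log2 6.41, SE 1.56, adjusted p = 0.0261, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and itf02g25880 (log2 6.26, SE 1.55, adjusted p = 0.0271, same edgeR test). Both levels were set largely by IbPep1 replicate 3. In that library itf06g10940 stood at 144 CPM, against 1.69 to 12.4 CPM in the other 3, and itf02g25880 at 13.5 CPM, against 0.0967 to 1.28 CPM. In water the means were 0.478 ± 0.796 and 0.0451 ± 0.0344 CPM (SD, n = 4), the second of them below the floor of 3 counts. For itf02g25880, IbPep1 replicate 1 and water replicate 3 each had 2 counts (0.0967 and 0.0835 CPM). Only the scaling kept the 2 groups of this gene from overlapping. Without IbPep1 replicate 3 the log2 fold change of itf06g10940 was 4.13 and no longer passed the threshold, and itf02g25880 was too low to be tested. Without water replicate 3, where itf06g10940 stood at 1.67 CPM against at most 0.154 CPM in the other water libraries, its fitted log2 fold change was 9.00. Leaving out water replicate 1, 2 or 4 also ended both calls, with log2 fold changes of 6.02, 6.14 and 6.04 for itf06g10940 and of 5.86, 6.31 and 6.26 for itf02g25880. With limma-voom neither gene passed the threshold (6.23 and 4.25).

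Of the genes that fell, itf01g01620 went from 1.99 ± 1.26 to 0.0878 ± 0.0763 CPM, below the floor, with 3, 0, 4 and 1 counts in the IbPep1 libraries (log2 -4.35, SE 0.92, adjusted p = 0.0164, same edgeR test). The level of itf09g08300 went from 34.2 ± 30.8 to 2.51 ± 0.494 CPM (log2 -3.76, SE 0.85, adjusted p = 0.0201, same edgeR test). In water replicate 3 these genes stood at 0.209 and 3.30 CPM, against at least 2.20 and 13.9 CPM in the other water libraries. With limma-voom neither passed the threshold (-3.99 and -3.003). The call of itf09g08300 was also lost without water replicate 1 or 4 (log2 -3.17 and -3.52) and without IbPep1 replicate 1 or 2 (log2 -3.69 and -3.92).

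Without water replicate 3, 6058 genes were called for IbPep1, including 2621 of the 2670. On 6014 of them that library lay at a median of 0.710 of the way from the other water libraries (0) to the IbPep1 libraries (1). The count was 839, 531 and 536 without water replicates 1, 2 and 4, and 911, 696, 1518 and 1746 without IbPep1 replicates 1, 2, 3 and 4. DESeq2 called 4554 genes. Of the 2670 genes, 84.9% had no overlap between the groups, against 19.6% of all genes tested and 2.86% by chance. Here too the share follows largely from the choice of genes and is no separate support.

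**Figure D2:**
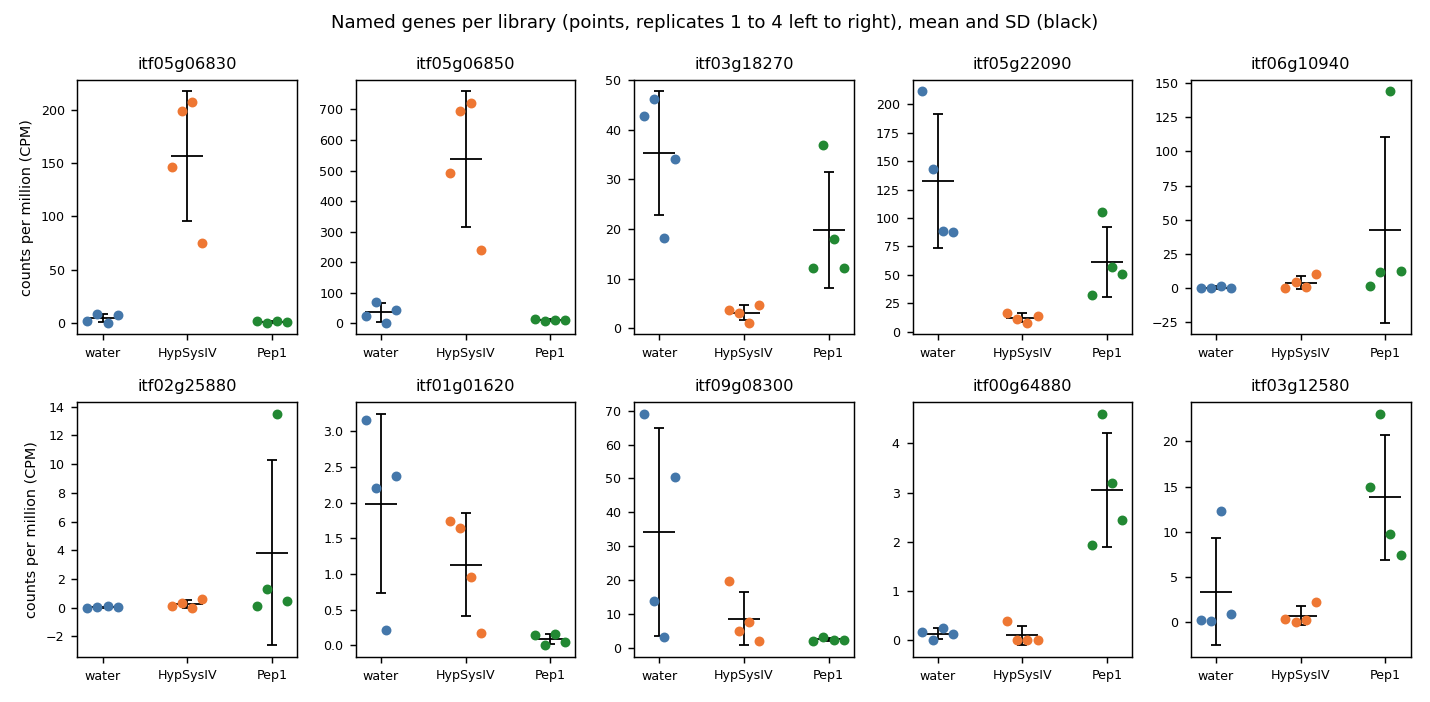
CPM of the 10 named genes in each library, as points for replicates 1 to 4 of each group from left to right, with the mean (horizontal bar) and SD (vertical bar, n = 4) in black. With IbHypSysIV, itf05g06830 averaged 157 CPM, against 4.84 in water and 1.32 with IbPep1, and the level of itf06g10940 with IbPep1 rests mostly on replicate 3, at 144 CPM.

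Set directly against each other, the peptides differed in 3674 genes, of which 1555 were higher and 2119 lower with IbPep1 than with IbHypSysIV. At least 2-fold differences were found in 728 genes upward and 713 downward. The 2 genes named above as raised by IbHypSysIV were also the 2 that the naming rule placed furthest down in IbPep1. The level of itf05g06830 was 1.32 ± 0.892 CPM with IbPep1, 116-fold lower than with IbHypSysIV (log2 -6.85, SE 0.81, adjusted p = 0.000630, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The level of itf05g06850 was 10.2 ± 2.71 CPM, 52.6-fold lower (log2 -5.72, SE 0.84, adjusted p = 0.00195, same edgeR test). Both kept their direction and their call in all 17 alternatives run for them. Against water, IbPep1 gave them log2 fold changes of -1.83 and -1.79, which did not pass the threshold (adjusted p = 0.109 for each, same edgeR test).

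In the other direction, itf00g64880 stood at 3.05 ± 1.16 CPM with IbPep1 and had 9 counts in IbHypSysIV replicate 1 and 0 in the other 3 libraries of that group (log2 4.75, SE 0.84, adjusted p = 0.00478, same edgeR test). The IbHypSysIV mean was below the floor of 3 counts, so this fold change is a fitted value set by that library and the prior count. Without IbHypSysIV replicate 1 the fitted value was 9.03. The call of itf00g64880 was lost with the replicate block (log2 3.84, adjusted p = 0.0934, same edgeR test). The level of itf03g12580 was 13.8 ± 6.92 CPM with IbPep1 and 0.733 ± 1.03 CPM with IbHypSysIV (log2 4.30, SE 1.25, adjusted p = 0.0366, same edgeR test). In water it was 12.3 CPM in replicate 3 and at most 0.960 CPM in the other 3. Its call was lost without IbHypSysIV replicate 1, 2 or 3 (log2 4.09, 3.91 and 3.96) and without IbPep1 replicate 1 or 2 (log2 4.25 and 3.92), and without IbHypSysIV replicate 4 the log2 fold change was 5.88 and still passed.

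Of the 3674 genes, 87.7% had no overlap between the groups, against 23.9% of all genes and 2.86% by chance. That share again follows largely from the choice of genes and is no separate support. The count was 2140 and 1890 without IbHypSysIV replicates 2 and 3, and 2135 and 1647 without IbPep1 replicates 1 and 2. With the replicate block it was 600, including 514 of the 3674. Among the 3674, 2162 had been called for neither peptide against water.

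Genes called for both peptides against water fell into 2 kinds. In 112 genes the change had the same direction, 61 higher and 51 lower with both, which is 20.9% of the IbHypSysIV calls and 4.19% of the IbPep1 calls. The median log2 fold changes of the 61 genes were 1.03 with IbHypSysIV and 0.97 with IbPep1, and those of the 51 were -1.001 and -0.94. Of these 112 genes, 5 differed between the peptides in the direct test, and in 92 the 95% interval of the difference lay within 1 log2 unit either way. Over all 23193 genes tested, 15.8% differed in the direct test and 13275 had such an interval. The 112 were chosen for changing the same way against the same water libraries, so small differences partly follow from the choice and are no separate support. In a further 27 genes the directions were opposite. Of these, 25 were higher with IbHypSysIV and lower with IbPep1, with medians of 1.07 and -1.26 on the log2 scale, and 2 were lower with IbHypSysIV and higher with IbPep1. All 27 were called in the direct test, which uses the same peptide libraries, so this follows from how they were chosen and is no separate support.

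A gene called for 1 peptide only was not thereby shown to respond differently to the other. Of the 397 genes called for IbHypSysIV only, 277 were called in the direct test, and of the 2531 called for IbPep1 only, 1203 were. These genes were chosen on libraries that the direct test uses too, and no value without a change was computed for either count.

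Both comparisons use the same water libraries. Unchanged groups simulated against shared controls gave 0 genes called for both, in either arrangement of directions, which is expected where nothing changes and sets no scale for the 112 or the 27. Independent lists of these sizes would share 15.5 genes higher with both, 15.3 lower with both and 30.9 with opposite directions. With the water libraries split 2 and 2 between the comparisons, 3 to 16 genes were called in the same direction and 0 to 26 in opposite directions over the 6 assignments. The lists themselves were mostly shorter there, 27 to 152 genes for IbHypSysIV and 68 to 3797 for IbPep1. Independent lists of those sizes would share 0.0193 to 3.33 genes higher with both, 0.0349 to 9.28 lower with both and 0.0593 to 12.3 with opposite directions. The IbPep1 lists held 919 to 3797 genes where water replicate 3 was a control for IbHypSysIV, and 68 to 112 where it was a control for IbPep1. The 26 genes with opposite directions came from the assignment with 3797. The fall from 112 is therefore no measure of a loss of overlap. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.354, against 0.497 for simulated unchanged groups and -0.0825 to 0.335 with split controls. The split values were -0.0825 to 0.0567 where water replicate 3 was a control for IbHypSysIV, and 0.311 to 0.335 where it was a control for IbPep1. That range is therefore set by 1 library. With shared controls the correlation was 0.542 without water replicate 3, for which the simulated value, made with 4 water libraries, is no comparison. The covariance was 0.113, against 0.0562 simulated, a difference of 0.0572, and -0.0385 to 0.115 with split controls. The split covariances divided in the same way, into -0.0385 to 0.0236 and 0.109 to 0.115. Taking the spread of the water libraries themselves in place of the simulation, the controls contributed 0.0593, or 0.0382 when computed without water replicate 3.

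The count of 112 was 12, 14, 476 and 22 without water replicates 1, 2, 3 and 4. It was 177, 10 and 62 without IbHypSysIV replicates 2, 3 and 4, 44 and 45 without IbPep1 replicates 1 and 2, and 495 with DESeq2. The 27 genes with opposite directions became 2, 6, 47 and 4 without water replicates 1 to 4, 17, 17 and 1 without IbHypSysIV replicates 1, 2 and 3, and 12, 11 and 16 without IbPep1 replicates 1, 2 and 4. DESeq2 gave 74 such genes.

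**Figure D3:**
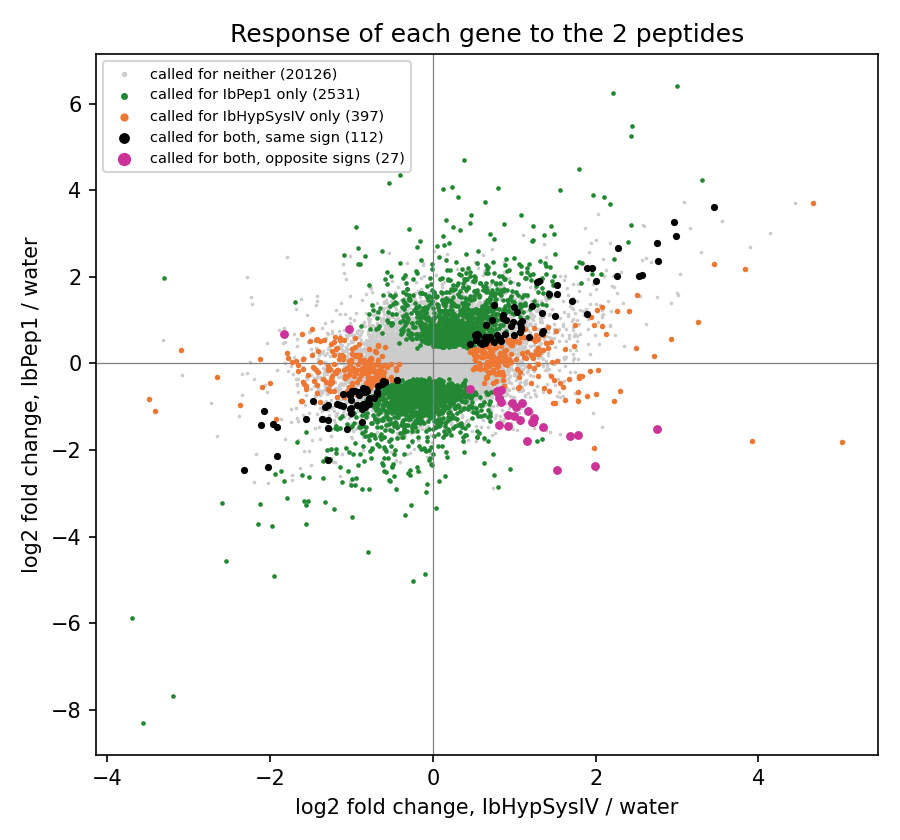
Log2 fold change against water of each of the 23193 genes with IbHypSysIV (horizontal axis) and with IbPep1 (vertical axis), coloured by the comparisons in which it was called. The 112 genes called for both with the same sign lie in the lower left and upper right, and 25 of the 27 called with opposite signs lie in the lower right. Genes near the floor have fitted values that depend on the prior count.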

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

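The tests of a wrong label, of a single outlying library and of a library batch were chosen after the results they bear on had been seen; the tests of depth and of other splits were chosen before. Outliers were sought in 45 groups of 4 values by the gap of the extreme value, and 8 were found. The limit used gives about 1 in 20 groups for independent, normally distributed values. Most of the 45 groups were CPM of named genes, chosen for large changes in these same libraries. The 8 are therefore not shown to exceed chance.

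Water replicate 3 had a mean correlation of 0.943 with its own group, far below the other water libraries, and held outlying levels of itf06g10940 (1.67 CPM) and itf03g12580 (12.3 CPM). Depth is argued against by a gap of 0.0301, after thinning to the smallest total, between its highest correlation with another water library and the lowest among those, and a swap with an IbPep1 library by the median positions of the IbPep1 libraries, each held out together with it, which were at least 0.833 on the genes then called for IbPep1 (0 at water, 1 at IbPep1). An IbHypSysIV-treated leaf with a water label is argued against as well by the genes called between the peptides (0 at IbHypSysIV, 1 at IbPep1). On these, water replicate 3 lay at 0.725 or more in fits that held out an IbHypSysIV library. Those libraries lay at -0.209 to 0.383. The levels of itf05g06830 (0.459 CPM) and itf05g06850 (1.67 CPM) in water replicate 3 were below those of every IbHypSysIV library. The naming rule required this of every water library, so it is no separate support. An IbPep1-treated leaf with a water label and a water-treated leaf in a different state cannot be told apart. On 6014 genes called for IbPep1, water replicate 3 lay at a median of 0.710 (bootstrap interval 0.699 to 0.722). That interval resampled genes, which are not independent, and does not measure how far a library's position varies. With 1 further library held out the position was 0.658 to 0.736. This is between the IbPep1 libraries and the other water libraries. The latter, held out in turn on their own sets of called genes, lay at -0.0190 to 0.252. On genes called for IbHypSysIV, water replicate 3 lay at 0.472. Its deviations from its group mean correlated at 0.397 with those of IbHypSysIV replicate 4 and at 0.261 with those of IbPep1 replicate 3. With the other peptide libraries they correlated at -0.313 to -0.0378, and those of the 2 named libraries correlated with each other at 0.481. Each of these 3 libraries had the lowest share of counts in the most abundant gene within its group (2.29%, 2.05% and 1.61%). A difference that cuts across the groups therefore stays open too. No biological explanation was tested, since the labels give the water libraries no difference.

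For IbPep1 against water, 1 of 35 splits, the real one, reached 2670 genes and the next highest gave 4, which argues against chance. The same holds for IbPep1 against IbHypSysIV, where 1 of 35 splits reached 3674 and the highest other gave 0 by edgeR's test. Chance is not excluded by this, since 1 of 35 is the lowest share the test can give. Splits that mix the groups also put any group difference into the spread, which lowers their counts. For IbHypSysIV against water the test does not argue against chance, since 2 of 35 splits reached 536. The other one exchanged water replicate 3 with IbHypSysIV replicate 2 and gave 834 genes, so the libraries hold a structure beyond their labels, and the next highest gave 34.

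IbPep1 changed 4.98 times as many genes against water as IbHypSysIV did, and the ratio was 2.56 by DESeq2's Wald test, 14.4 in fits of only the 2 groups and 9.14 at an adjusted p under 0.01 by edgeR, while the replicate block called 0 genes for IbHypSysIV. With all libraries thinned to the smallest total the median ratio was 4.94 over 5 draws (4.77 to 5.34), which argues against depth. Leaving out any 1 of the 12 libraries gave ratios of 2.08 (without IbPep1 replicate 2) to 53.1 (without IbHypSysIV replicate 3), which argues against a single outlying library as the whole cause, although the size of the ratio rests on single libraries. A library batch cannot be told apart from the treatment, because 0 pairs of groups have overlapping library numbers. A larger response to IbPep1 at 1 h may account for the ratio of 4.98 and stays open as a hypothesis, as do differences in dose, which the labels do not give.

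IbPep1 replicate 3 was an outlier on the second principal component (32.1) and in its levels of itf06g10940 (144 CPM) and itf02g25880 (13.5 CPM). In IbHypSysIV, replicate 1 was the only library with reads of itf00g64880 (0.401 CPM), and replicate 4 stood out in itf03g12580 (2.27 CPM).

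Responses that differed between the peptides in the direct edgeR test were also marked. The IbPep1 minus IbHypSysIV log2 difference was -6.85 for itf05g06830, -5.72 for itf05g06850 and -3.56 for itf01g01620. It was 2.66 for itf03g18270, 2.31 for itf05g22090, 4.04 for itf02g25880, 4.75 for itf00g64880 and 4.30 for itf03g12580. The peptide groups overlapped for itf02g25880, with 0.582 CPM in IbHypSysIV replicate 4 against 0.0967 and 0.481 CPM in IbPep1 replicates 1 and 4. Its difference rests largely on IbPep1 replicate 3, at 13.5 CPM. The 27 genes called with opposite signs against water were all called directly, which follows from their selection on the same libraries.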

How the results depend on the processing

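Leaving out water replicate 3, IbHypSysIV replicate 4 and IbPep1 replicate 3 together was chosen after the data had been seen. Other scalings, other filters and limma-voom kept every count of called genes within 1.5 times its value, but the balance for IbPep1 against water turned to more genes higher than lower with upper-quartile scaling (1445 and 1274), limma-voom (1350 and 1223), only the 2 groups (1268 and 1251), the block (1771 and 1560) and without IbPep1 replicate 4 (913 and 833). DESeq2's Wald test gave 1779 genes for IbHypSysIV, 4554 for IbPep1 and 495 shared in direction; among them were 533 of the 536 and 2667 of the 2670 edgeR calls, and the cause was not tested. An adjusted p under 0.01 left 28, 256 and, for IbPep1 against IbHypSysIV, 836 genes. A fit of only the 2 groups gave 175 genes for IbHypSysIV. Requiring at least 2-fold in both left 39 shared genes. Without the 3 libraries together, 1153, 6569 and 5530 genes were called in the 3 comparisons, and 508 were shared. They included 432 of the 536, 2537 of the 2670 and 3342 of the 3674 calls. Leaving out single libraries gave 34 (without IbHypSysIV replicate 3) to 970 genes (without water replicate 3) for IbHypSysIV and 531 (without water replicate 2) to 6058 (without water replicate 3) for IbPep1. For IbPep1 against IbHypSysIV it gave 1647 (without IbPep1 replicate 2) to 3669, and for the shared genes 10 (without IbHypSysIV replicate 3) to 476 (without water replicate 3). The correlation of fold changes ranged from 0.245 (without IbHypSysIV replicate 4) to 0.542 (without water replicate 3). No named gene changed sign. The replicate block on the title numbers called 0 genes for IbHypSysIV (2099 at an unadjusted p under 0.05, edgeR). Without the block DESeq2 called 1779 and limma-voom 518. With it, 600 were called between the peptides, 0 were shared and 3331 were called for IbPep1. The block leaves 3 residual degrees of freedom in place of 9. The 4 libraries with a number found in 1 group only add nothing to its comparisons. They are water replicate 3, IbHypSysIV replicates 3 and 4 and IbPep1 replicate 4. The title numbers do not pair the libraries. Deviations of the 7 same-numbered pairs correlated at -0.0763 to 0.140, and 0 of 8 libraries correlated best with their own number. Gene lists were not run for want of gene descriptions, nor pseudocounts, since the file holds counts. The gene itf02g25880 was too low to be tested in 4 of the 17 alternatives.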

Other observations

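The positions of held-out libraries were looked at after the results had been seen; the tests on neighbouring identifiers were chosen before. The IbHypSysIV libraries differed in where they lay between water and IbPep1 on genes called for IbPep1. Each was held out together with water replicate 3, leaving 5189 to 6973 genes called for IbPep1. The median position, 0 at water and 1 at IbPep1, was 0.455, 0.000309, 0.369 and 0.568 for replicates 1, 2, 3 and 4. In these same fits water replicate 3 lay at 0.704 to 0.716. The other water libraries, held out in turn on 2467 to 4385 genes, lay at -0.0190 to 0.252. A position above 0 is therefore no measure of a partial response like that to IbPep1.

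Among 17995 pairs of tested genes with consecutive identifiers, 218 had both members called in 1 direction with IbPep1, more than in any of 1000 shuffles of the calls among genes of similar abundance (highest 155). Another 104 pairs had both called in opposite directions, within the range of the shuffles (highest 161). For IbHypSysIV 12 pairs had both members called in 1 direction, against a shuffled median of 5. Few shuffles reached that count (permutation p = 0.00400, one-sided), so it was more than the shuffles usually gave. It lay within 1 SD (2.15) of the highest shuffle, 13, so the excess rests on few pairs and is less clear than for IbPep1. Reads shared between near-identical copies may hold part of the pairs, and this stays open: the ratio of the members' counts varied by more than 2 times its counting variance in 197 of the 229 pairs called with either peptide, which argues against a fixed ratio in those but not in the rest. Joint regulation of neighbouring genes is a candidate explanation that no value here separates from it, and the order of the identifiers along a genome was not checked.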
